A study of Mus musculus with 8 samples.

How the data were processed

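Gene expression was measured by RNA sequencing in 8 mouse libraries that the labels name pulmonary endothelial cells from lung, 4 labelled Ad-control and 4 labelled Ad-KLK8. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The authors deposited 1 table of RPKM values (reads per kilobase of gene length, scaled to the reads of the library) for 21878 genes, with a column per library and no further scaling between libraries on record. Per the submitters' processing notes, Trimmomatic, HISAT2, SAMtools, Cufflinks and DESeq were used, with no versions or roles given, on the human build GRCh38, whereas the gene symbols and identifiers of the table are those of mouse. Because these disagree, no coordinates are given and the annotation version is not given in the sources used here. How reads of gene families or overlapping genes were assigned is likewise not given, so such genes are named as uncertain.

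Groups and replicate numbers were taken from the labels. The comparison, its test, its threshold, the gene lists, the rule for named genes and the alternatives other than those said to be added were fixed before the data were examined. Calendar dates stood in place of 12 gene names, and all 12 were restored from their Entrez identifiers. Of the 21878 genes, 17461 had a value above 0 in at least 1 library. In each of these the deposited values were whole multiples of the value of 1 read, within a tolerance of 0.001 read, so that reads per gene and library could be recovered. On a simulated table the recovery was exact for 99.68% of the 6790 genes with reads in every library. Simulated genes with a count of 0 in some library were not scored. The recovered gene-assigned reads were 16761367, 15771803, 16343646 and 16225837 for Ad-control replicates 1 to 4 and 18496324, 17785884, 18539808 and 18702922 for Ad-KLK8 replicates 1 to 4. The genes of the table held 99.9% of the reads in the RPKM denominator. A tested gene had a median of 573 reads per library.

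The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(RPKM + 1), over the 11998 genes with a mean of at least 0.5 RPKM over all libraries, with group as the only term. P-values were adjusted after Benjamini and Hochberg at 0.05, and a second count required a change of at least 2-fold. A fold change on the log2(RPKM + 1) scale understates the change of low genes. Klk8, the gene in the treatment's name, was also tested with a two-sided exact permutation test of the difference in mean log2(RPKM + 1).

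Of 43 gene lists, 33 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Camera sets a list against all other genes, while fry asks whether its members move on balance in 1 direction. The count of members past the threshold was also taken adjusted over the list alone. Pathway codes in the deposited table gave 292 KEGG pathways with enough tested genes, which were tested in the same way. This pathway test was added after seeing the data. Python 3.11.15 with scipy 1.17.1 and pandas 2.3.3 was used for tables and exact tests. GC content came from the transcripts of GENCODE mouse release M21, matched by symbol, and served only for a check of gene length and GC content.

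The named genes are Klk8, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 RPKM and no overlap between the groups, and up to 4 members with the smallest adjusted p from each described list. To these come 10 genes of endothelial barrier, adhesion and protease-activated receptors fixed in advance whatever their result, which are Cdh5, Cldn5, Ocln, Tjp1, Sdc1, Icam1, Vcam1, Sele, F2r and F2rl1. Some genes that this rule names are not reported here. Alternatives were other pseudocounts, other filters, rescaling to TPM, upper-quartile, median-of-ratios and quantile scaling, other limma priors, sample weights, the replicate number as a block, and leaving out each library in turn. A voom fit of the recovered reads and a fit with closely similar libraries averaged were added after seeing the data. The groups were also redrawn in all 35 splits of the 8 libraries into 4 and 4.

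The script was tested on simulated values of 11970 genes. Their counts were drawn independently at 1 dispersion for all genes (0.0028, the median estimate from the real libraries). It recovered 68% of genes changed 1.25-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold in a simulated comparison of the same size. Of its calls, 2.67% were unchanged genes. These rates hold for the simulation only, as few of its genes changed and no simulated library stood apart from its group. Replicates were compared before use. Libraries Ad-control 1 and 3 differed by a chi-square per degree of freedom of 2.45, and Ad-KLK8 1, 3 and 4 by 2.12 to 2.63, against 6.32 to 19.6 for the other pairs within a group. As these values exceed sampling noise, all 8 libraries were kept as separate replicates, though such values do not show that the libraries are independent.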

Results

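RNA sequencing was analysed in 8 mouse libraries whose labels name pulmonary endothelial cells from lung. The labels put 4 libraries in a group named Ad-control and 4 in a group named Ad-KLK8, and they do not expand the prefix Ad. The series concerns kallikrein-related peptidase 8 (KLK8), a secreted serine protease, and the pulmonary endothelium in lung injury during endotoxemia. The comparison asked which transcripts differed between the libraries labelled Ad-KLK8 and those labelled Ad-control. The deposited RPKM values of 21878 genes corresponded to whole reads, and the recovered gene-assigned reads numbered 15771803 to 16761367 per library labelled Ad-control and 17785884 to 18702922 per library labelled Ad-KLK8. A count of 0 therefore allowed up to 0.16 to 0.19 RPM in a library, which covers counting error only. Levels below are mean RPKM ± SD with n = 4 per group, the libraries labelled Ad-control first. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

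Klk8 itself was among the most abundant transcripts in every library of both groups. Its level was 1135, 1403, 1232 and 1422 RPKM in the libraries labelled Ad-control and 1159, 3263, 1354 and 1276 RPKM in those labelled Ad-KLK8. The group means were 1298 ± 138 and 1763 ± 1003 RPKM (SD, n = 4). By RPKM it ranked 13 to 17 among all genes in the libraries labelled Ad-control and 5 to 22 in those labelled Ad-KLK8. The mean log2 difference was 0.31 and did not exceed the spread between libraries (two-sided exact permutation p = 0.657 over 70 arrangements, of which the smallest possible p is 0.0286). Without the library labelled Ad-KLK8 replicate 2 the difference was −0.04 (exact p = 0.771). The gene named in the treatment therefore did not separate the groups, and each direction given here rests on the labels alone. The species and sequence of any introduced KLK8 are not given in the sources used here.

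**Figure D1:**
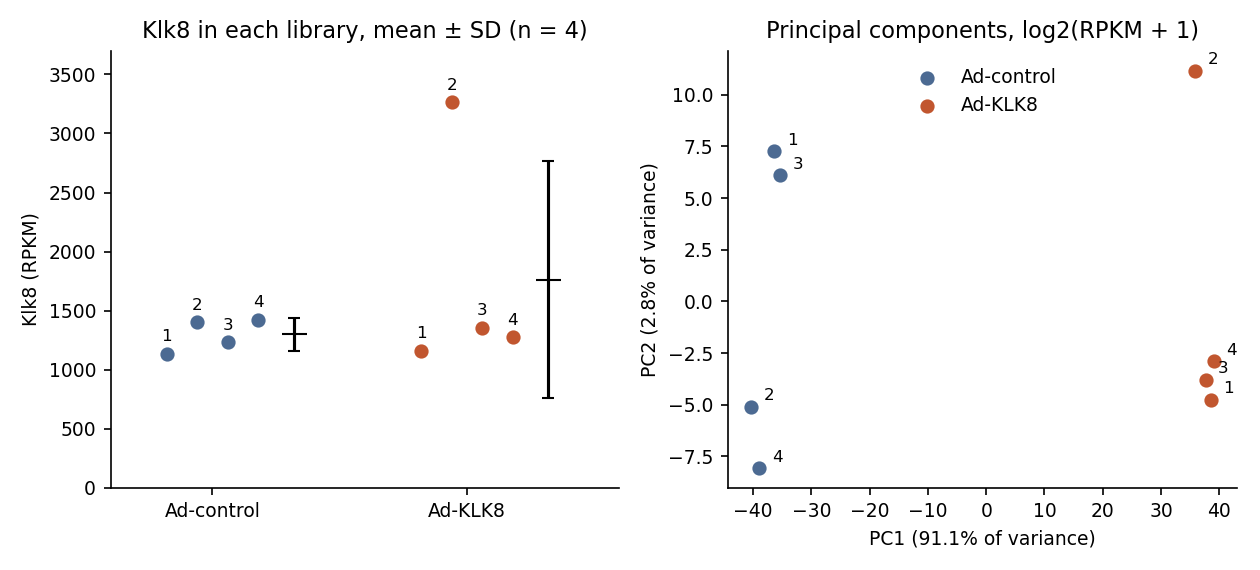
Left, Klk8 level (RPKM) in each of the 8 libraries, numbered by replicate, with the group mean and SD in black (n = 4). Right, the same libraries on the first and second principal components of log2(RPKM + 1), where the 2 labelled groups lie apart on a component with 91.1% of the variance while Klk8 overlaps between them.

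The 2 labelled groups differed across most of the measured transcriptome. The first principal component held 91.1% of the variance and parted the groups, and the second held 2.8%. Pearson's r across genes was 0.993 to 0.998 within groups and 0.928 to 0.941 between them (genes are not independent replicates). Of 11998 genes with a mean of at least 0.5 RPKM, 9322 passed an adjusted p of 0.05 with limma, 3079 higher and 6243 lower in the libraries labelled Ad-KLK8. A change of at least 2-fold on the log2(RPKM + 1) scale was found for 1464 of them, 282 higher and 1182 lower. The median log2 change of all tested genes was −0.19, and it was −0.002 after median-of-ratios scaling. That scaling gave 9249 genes, 4609 higher and 4640 lower, which moved the share of higher genes from 33.0% to 49.8%. It moved the 2-fold split to 494 higher and 816 lower. Upper-quartile scaling gave 4354 higher and 4913 lower genes, and quantile normalization 4892 and 4373. Counts or medians of most gene lists are therefore given under both the main and the median-of-ratios scaling. The 10 most abundant genes took 4.56% to 4.83% of reads in the libraries labelled Ad-control and 7.05% to 7.84% in those labelled Ad-KLK8.

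The 10 largest rises included markers from the fibroblast and mesothelium lists. Lum, a small leucine-rich proteoglycan of connective tissue, rose from 2.82 ± 0.694 to 35.6 ± 4.79 RPKM (SD, n = 4), and Gas1, a membrane protein linked to growth arrest, from 24.9 ± 5.03 to 211 ± 4.59. Upk3b, a mesothelial uroplakin, rose from 69.9 ± 13.9 to 405 ± 19.5, and Lrrn4, another mesothelial membrane protein, from 5.13 ± 1.28 to 34.3 ± 0.473. The transcription factors Tcf21, which marks mesenchymal progenitors, and Maf rose from 2.83 ± 0.649 to 25.8 ± 1.88 and from 11.8 ± 1.77 to 87.7 ± 4.55. Wnt4, a secreted signalling protein, rose from 7.20 ± 2.26 to 48.1 ± 4.95. Angptl7, a secreted angiopoietin-like protein, rose from 1.59 ± 0.246 to 20.8 ± 0.959 RPKM and Fam180a from 1.01 ± 0.334 to 13.4 ± 0.485. H2-T3, a non-classical MHC gene, rose from 2.11 ± 1.86 to 15.5 ± 3.74, and its family shares sequence, so its level is uncertain. Limma's adjusted p for these 10 genes lay between 5.19e-10 for Angptl7 and 8.64e-05 for H2-T3.

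The 10 largest falls included genes of epithelial cornification, growth factors and cell cycle genes. The cornified envelope precursors Sprr2h, Sprr1a and Crct1 fell from 65.4 ± 18 to 0.252 ± 0.238 RPKM (SD, n = 4), from 90.2 ± 10.6 to 2.58 ± 0.76 and from 25.1 ± 0.871 to 0.395 ± 0.232. Reads of Sprr2h may be split with close family members, which leaves its level uncertain. Areg, an EGF receptor ligand, fell from 17.5 ± 1.77 to 0.156 ± 0.0758 RPKM, and Pgf, a ligand of the VEGF family, from 29 ± 15 to 0.66 ± 0.244. Spp1, the secreted phosphoprotein osteopontin, fell from 264 ± 50.5 to 15.7 ± 1.85. Ccne2, a cyclin of S-phase entry, fell from 20 ± 2.44 to 0.322 ± 0.149, and Fbxo5, an inhibitor of the anaphase-promoting complex, from 20.6 ± 1.99 to 0.877 ± 0.314. Gem, a small GTP-binding protein, fell from 23.7 ± 4.99 to 0.763 ± 0.268 RPKM, and Krt19, a keratin of simple epithelium and mesothelium, from 22.5 ± 8.43 to 0.758 ± 0.213. Limma's adjusted p for these 10 genes lay between 2.65e-10 for Areg and 2.67e-07 for Pgf.

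DNA replication genes formed the most uniform group. All 25 tested members fell, 24 of them at least 2-fold, with a median log2 change of −2.43 (−2.22 after median-of-ratios scaling). The count of 25 was the same adjusted over the list alone. Pcna, the sliding clamp of DNA polymerase, fell from 159 ± 5.82 to 21.9 ± 1.03 RPKM (SD, n = 4). The replicative helicase subunits Mcm3 and Mcm6 fell from 72 ± 2 to 5.51 ± 0.594 and from 70.5 ± 2.24 to 12.2 ± 0.483, and Uhrf1, which maintains DNA methylation, from 22.2 ± 2.16 to 1.52 ± 0.127. Camera with its preset correlation gave an adjusted p of 5.82e-09 for the list, and adjusted p = 0.564 with an estimated correlation. In the G2/M and mitosis list 22 of 23 members fell, 16 of them at least 2-fold, with a median of −1.20 (−1.05 after median-of-ratios scaling) and the same count adjusted over the list alone. The exception was Ccnb2 (limma adjusted p = 0.583), chosen after its values were seen. Cdk1, the mitotic kinase, fell from 19.6 ± 1.22 to 5.17 ± 1.05 RPKM, and its partner Ccna2 from 9.48 ± 1.11 to 1.60 ± 0.442. Mki67, a proliferation marker, and Top2a, which untangles DNA before division, fell from 8.72 ± 1.71 to 1.60 ± 0.347 and from 16.3 ± 2.5 to 3.93 ± 1.06. The list had a camera adjusted p of 0.00144, and adjusted p = 0.690 with an estimated correlation.

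Immediate-early genes of MAPK signalling and their feedback regulators were lower as a group. Of 19 tested members 17 fell, 1 rose and 1 did not pass, with the same count adjusted over the list alone and a median of −0.64. After median-of-ratios scaling 15 fell and 1 rose, with a median of −0.42. The AP-1 subunits Fosl1 and Jun fell from 65.2 ± 5.71 to 11.6 ± 1.23 RPKM (SD, n = 4) and from 76.3 ± 4.22 to 30.5 ± 1.13. The MAPK phosphatases Dusp1 and Dusp4 fell from 58.1 ± 4.11 to 28.7 ± 0.752 and from 58.2 ± 3.74 to 28.8 ± 1.12. For the list, camera's adjusted p was 0.0056, and adjusted p = 0.564 with an estimated correlation.

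Apoptosis regulators also fell, in 14 of 19 tested members with none higher, and adjusted over the list alone the count was also 14. The median log2 change was −0.40, and after median-of-ratios scaling 11 fell and 2 rose, with a median of −0.19. The BH3-only genes Pmaip1, Bbc3 and Bid, which promote cell death, fell from 51.5 ± 2.18 to 11.3 ± 1.05 RPKM (SD, n = 4), from 22.7 ± 1.62 to 9.47 ± 0.544 and from 19.3 ± 0.746 to 10.7 ± 0.865. The camera adjusted p of the list was 0.0467, and adjusted p = 0.388 with an estimated correlation. The preset call was also lost after upper-quartile scaling (0.116), median-of-ratios scaling (0.13) and quantile normalization (0.0606), and without the library labelled Ad-KLK8 replicate 3 (0.0514) or 4 (0.0526). Over 20 alternative settings with the preset correlation the adjusted p was 0.0158 to 0.13.

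Extracellular matrix and basement membrane genes were mostly higher. Of 25 tested members 17 rose, 7 fell and 1 did not pass, with the same count adjusted over the list alone and a median of 0.42 (0.64 after median-of-ratios scaling, with 17 higher and 6 lower). The metalloproteinase inhibitors Timp3 and Timp2 rose from 93.2 ± 2.96 to 477 ± 49.1 RPKM (SD, n = 4) and from 185 ± 7.55 to 446 ± 17.4. Nid2, a basement membrane glycoprotein, rose from 19.2 ± 1.52 to 58.5 ± 3.62, and Mmp14, a membrane-bound metalloproteinase, from 124 ± 5.65 to 235 ± 2.76. Camera gave an adjusted p of 0.00144, and adjusted p = 0.388 with an estimated correlation. The call was lost after quantile normalization (0.0812), the highest value of 20 settings that began at 0.000471.

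Markers of fibroblasts and mesothelium moved with the matrix genes. Of 12 fibroblast markers 8 rose, 3 fell and 1 did not pass, with the same count adjusted over the list alone and a median of 0.96 (1.18 after median-of-ratios scaling). Besides Lum and Tcf21, the matrix proteoglycan gene Dcn rose from 309 ± 49.2 to 1084 ± 46.7 RPKM (SD, n = 4) and the receptor gene Pdgfrb from 15.7 ± 0.54 to 34.6 ± 2.13. Their camera adjusted p was 0.00226, and adjusted p = 0.305 with an estimated correlation. Of 5 tested mesothelium markers 4 rose and Krt19 fell, both over all genes and adjusted over the list alone, with a median of 0.98 (1.19 after median-of-ratios scaling). Among them Wt1, a mesothelial transcription factor, rose from 78.3 ± 3.94 to 105 ± 4.75. The mesothelium list had a camera adjusted p of 0.0467, and adjusted p = 0.564 with an estimated correlation. That call was lost after upper-quartile scaling (0.13), median-of-ratios scaling (0.157) and quantile normalization (0.204), and without filter (0.0552) or at a minimum of 5 RPKM (0.0589). It was also lost without the library labelled Ad-control replicate 4 (0.0527) or Ad-KLK8 replicate 1 (0.078), 3 (0.0707) or 4 (0.0512), and the 20 settings ranged from 0.0232 to 0.204.

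Interferon-stimulated genes were higher or did not pass. Of 23 tested members 11 rose and 12 did not pass, with the same count adjusted over the list alone and a median of 0.35, and after median-of-ratios scaling 15 rose with a median of 0.57. Ifit1, an antiviral effector, rose from 309 ± 27.3 to 689 ± 154 RPKM (SD, n = 4), and Irf7, a transcription factor of the interferon response, from 432 ± 9.99 to 750 ± 63.9. Bst2, a membrane protein that tethers virions, rose from 1244 ± 38.6 to 1840 ± 131, and Parp9, an ADP-ribosyltransferase family member, from 39.4 ± 2.42 to 70.8 ± 9.64. Camera gave an adjusted p of 0.00144, and adjusted p = 0.690 with an estimated correlation. The call was lost after quantile normalization (0.0914), the highest value of 20 settings that began at 1.6e-08. The library labelled Ad-KLK8 replicate 2 was lower than the others of its group for Ifit1 (458.8 RPKM against 755.1 to 784), Irf7 (655.5 against 775.4 to 794.8) and Parp9 (56.37 against 74.4 to 76.38), and the value of 1.6e-08 came without it, with a list median of 0.44.

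Genes of cholesterol synthesis and SREBP2 signalling went in both directions. Of 20 tested members 11 rose, 5 fell and 4 did not pass, with the same count adjusted over the list alone and a median of 0.26. After median-of-ratios scaling 14 rose and 3 fell, with a median of 0.46. Srebf2, the transcription factor of the pathway, rose from 19.5 ± 0.875 to 32 ± 1.77 RPKM (SD, n = 4), while Dhcr7, a late enzyme of the pathway, fell from 17.8 ± 0.673 to 8.39 ± 0.503. Camera gave an adjusted p of 0.0229 for a rise of the list, and adjusted p = 0.690 with an estimated correlation. The call was lost after upper-quartile (0.0587) and median-of-ratios scaling (0.0685), and the lowest of the 20 settings was 0.0117.

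**Figure D2:**
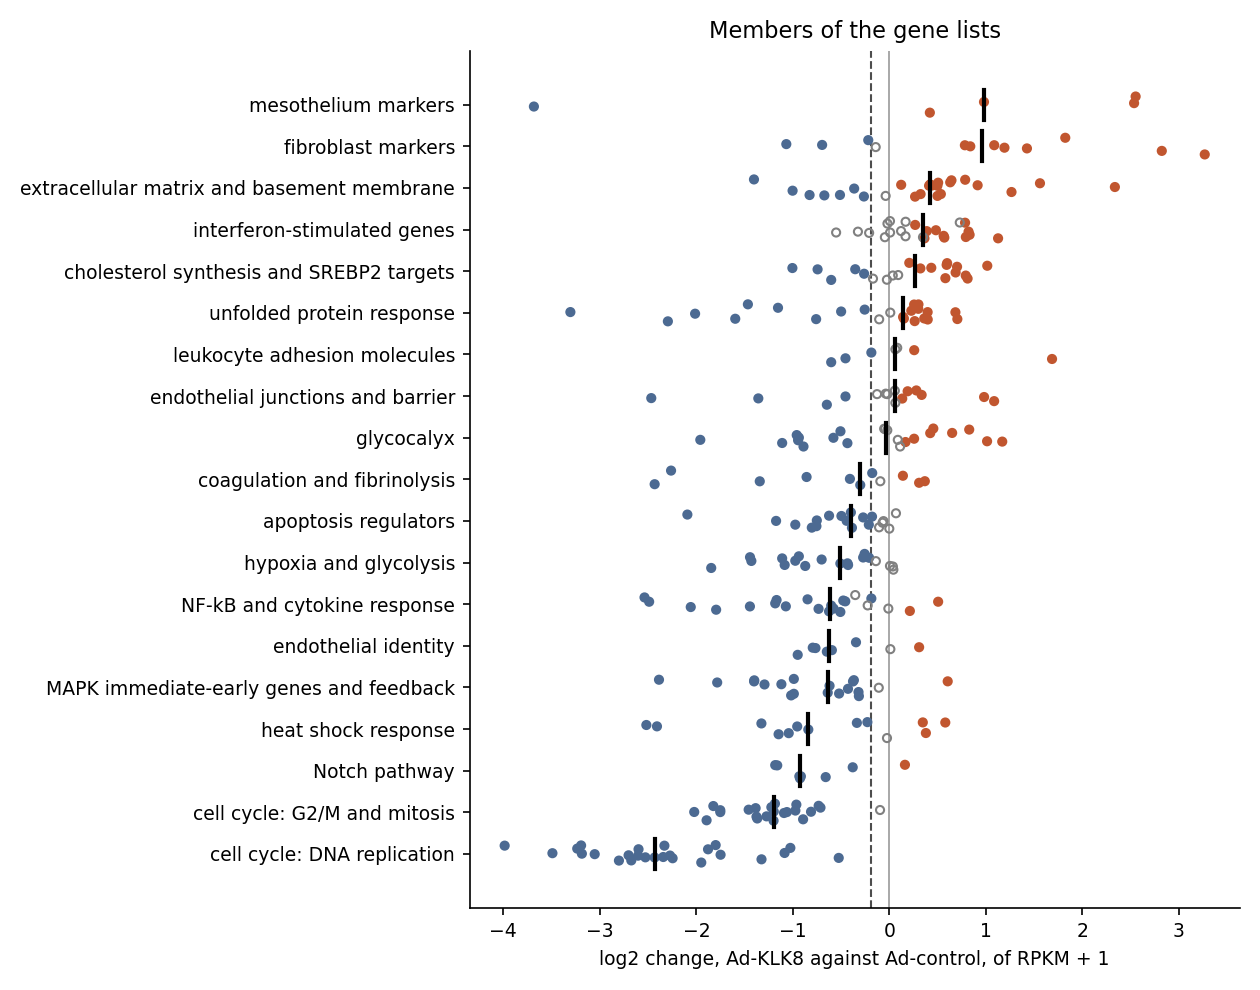
Log2 change of RPKM + 1 (libraries labelled Ad-KLK8 against Ad-control) of each tested member of the described gene lists with at least 5 tested genes. Filled points passed an adjusted p of 0.05 with limma (orange higher, blue lower), open points did not, bars mark list medians, and the dashed line marks the median of all tested genes at −0.189. The DNA replication list lies lowest, with a median of −2.43, while the glycocalyx median of −0.03 is 0.18 after median-of-ratios scaling.

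Most genes that define endothelial cells were low in both groups. Of 25 endothelial identity genes 17 stayed under a mean of 0.5 RPKM, including Cdh5, the adherens junction cadherin of endothelium, with 24 reads summed over the libraries labelled Ad-control and 3 over those labelled Ad-KLK8. The tight junction gene Cldn5 had 1 and 3 reads. The median level of the list was 0.11 RPKM in the libraries labelled Ad-control, against 19.8 RPKM for the fibroblast markers and 12.6 RPKM for 7 venous endothelium markers. A mean of at least 1 RPKM was reached by 7 identity genes. Among the 8 tested members 6 fell, 1 rose and 1 did not pass, with the same count adjusted over the list alone and a median of −0.62 (−0.47 after median-of-ratios scaling, with 5 lower and 1 higher). The transcription factor Fli1 fell from 1.65 ± 0.203 to 0.526 ± 0.0554 RPKM (SD, n = 4), and the adhesion molecule Esam from 20.8 ± 0.835 to 12.9 ± 1.11. The VEGF receptor Flt1 fell from 1.29 ± 0.319 to 0.176 ± 0.0413, and Ecscr, an endothelial surface protein, from 7.22 ± 0.461 to 3.84 ± 0.446. Camera did not call the list (adjusted p = 0.366, and adjusted p = 0.690 with an estimated correlation).

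**Figure D3:**
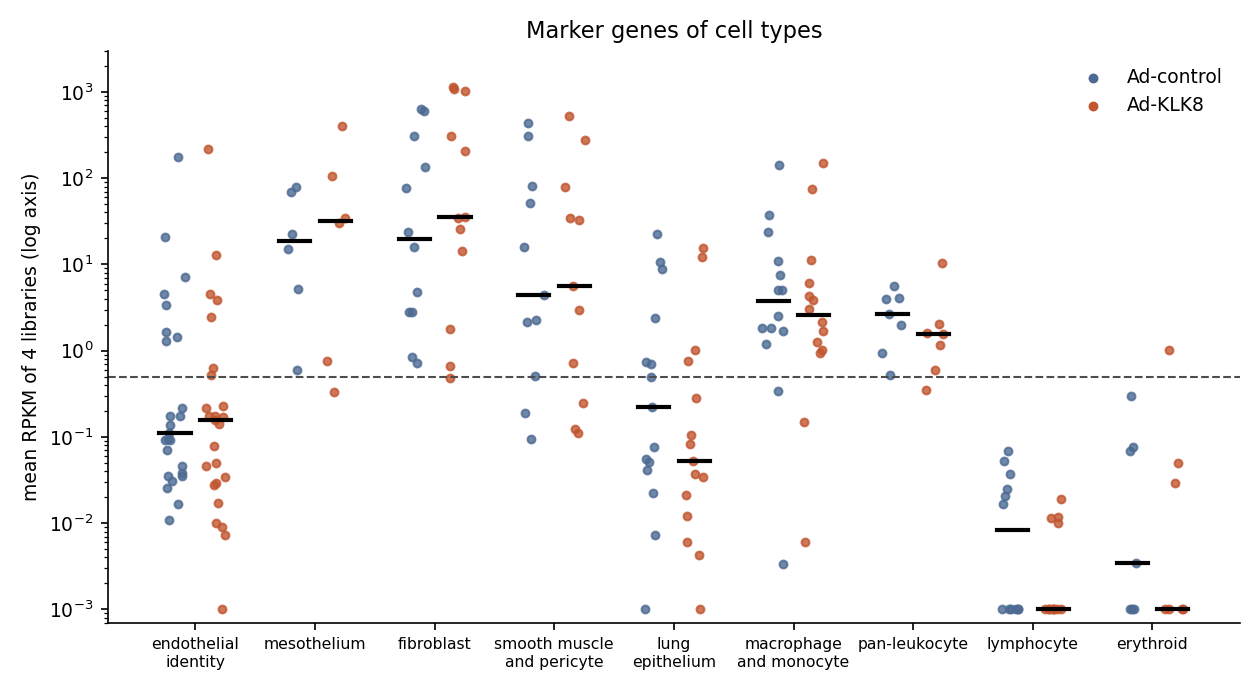
Mean level (RPKM of 4 libraries, log axis) of each marker gene of 9 cell-type lists in the libraries labelled Ad-control (blue) and Ad-KLK8 (orange), with list medians as bars, the dashed line at 0.5 RPKM, and values under 0.001 drawn at 0.001. Endothelial identity genes have a median of 0.11 RPKM in the libraries labelled Ad-control, far below the fibroblast markers at 19.8.

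Junction, glycocalyx and leukocyte adhesion genes went in both directions without a camera call for any of the lists. Fry, which does not subtract the shift of all genes, called the junction and glycocalyx lists lower (adjusted p = 0.00405 and 0.00199). It did not call the leukocyte adhesion list (0.72). Of 15 tested junction and barrier genes 6 rose, 4 fell and 5 did not pass (10 rose and 4 fell after median-of-ratios scaling). The plakoglobin gene Jup rose from 12.7 ± 0.788 to 28 ± 0.156 RPKM (SD, n = 4) and F11r, a junctional adhesion molecule, from 52.3 ± 3.31 to 104 ± 5.98. The sphingosine-1-phosphate receptor S1pr1 fell from 13 ± 1.86 to 1.52 ± 0.164, and the gap junction gene Gja1 from 66.5 ± 1.14 to 25.3 ± 1.54. Tjp1, which encodes the scaffold ZO-1, was 19.1 ± 0.856 and 19.9 ± 0.571 RPKM (limma adjusted p = 0.256, but 0.000119 for a log2 rise of 0.27 after median-of-ratios scaling), and Ocln had 41 and 30 reads in all. Of 22 glycocalyx genes 8 rose, 9 fell and 5 did not pass, whereas 13 rose and 9 fell after median-of-ratios scaling. The core proteins Hspg2 and Sdc4 rose from 48.1 ± 2.52 to 110 ± 9.22 and from 121 ± 10 to 244 ± 11.2. Sdc1, the shed syndecan of the endothelial surface, fell from 68.6 ± 1.85 to 31.3 ± 2.23, and the hyaluronan synthase Has2 from 6.25 ± 0.95 to 0.862 ± 0.219. Counts were the same adjusted over the list alone. Tested with camera, adjusted p was 0.256 and 0.381 for the 2 lists, and adjusted p = 0.564 and 0.690 with an estimated correlation, each with an upward direction although the mean log2 changes were −0.13 and −0.15.

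Of 7 tested leukocyte adhesion molecules 2 rose, 3 fell and 2 did not pass, with the same count adjusted over the list alone (4 rose and 2 fell after median-of-ratios scaling). Selp, the platelet and endothelial selectin, rose from 0.429 ± 0.232 to 3.64 ± 1.07 RPKM (SD, n = 4). Vcam1, which binds leukocyte integrins, fell from 459 ± 90.1 to 298 ± 26.3, and Jam2 from 0.805 ± 0.129 to 0.317 ± 0.0941, a call lost after quantile normalization (0.232), with a log2 change of −1.36 to −0.11 over the settings. Icam1 fell from 85.7 ± 2.27 to 75.3 ± 5.67, a log2 change of −0.19 that became 0.03 after median-of-ratios scaling and was not called there (limma adjusted p = 0.627), nor after upper-quartile scaling, with a range of −0.24 to 0.03 over the settings. Sele had 56 reads over the libraries labelled Ad-control and 4 over those labelled Ad-KLK8. The list itself was not called by camera (adjusted p = 0.515, and adjusted p = 0.690 with an estimated correlation).

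Cytokine and NF-kB response genes were mostly lower, but camera did not call the list. Of 22 tested members 17 fell, 2 rose and 3 did not pass, with the same count adjusted over the list alone and a median of −0.61 (16 fell and 2 rose after median-of-ratios scaling, median −0.41). The cytokine genes Il1a, Cxcl2 and Csf2 fell from 10.6 ± 1.17 to 1.78 ± 0.299 RPKM (SD, n = 4), from 14.3 ± 4.66 to 1.58 ± 0.34 and from 1.35 ± 0.275 to 0.0385 ± 0.0315. Tnfaip3, the feedback inhibitor A20, fell from 77.2 ± 10.5 to 27.7 ± 3.24. By camera the list had adjusted p = 0.0583, and adjusted p = 0.690 with an estimated correlation. The list was called after median-of-ratios scaling (0.035) and without the library labelled Ad-control replicate 1 (0.048) or 3 (0.0377) or Ad-KLK8 replicate 1 (0.0448), and passed in 9 of 20 settings, which ranged from 0.00503 to 0.112. Of 12 macrophage and monocyte markers 6 were lower, 1 was higher and 5 did not pass, a share of lower genes near that of all tested genes (6243 of 11998). After median-of-ratios scaling 2 were lower and 1 higher, against 4640 of 11998 lower over all tested genes. Camera did not call the list (adjusted p = 0.982).

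Coagulation and fibrinolysis genes included several protease regulators that fell. Of 11 tested members 7 fell, 3 rose and 1 did not pass, with the same count adjusted over the list alone and a median of −0.30 (5 fell and 3 rose after median-of-ratios scaling). Plau, the urokinase activator of plasminogen, fell from 32 ± 1.26 to 5.12 ± 0.287 RPKM (SD, n = 4). Its inhibitor Serpinb2 fell from 311 ± 27.2 to 64 ± 2.8, and Procr, the protein C receptor, from 106 ± 15.7 to 40.9 ± 3.78. Camera gave adjusted p = 0.515, and adjusted p = 0.690 with an estimated correlation.

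The tested members of the hypoxia and glycolysis, heat shock and Notch lists were mostly lower, without a camera call in the main setting. Fry, which does not subtract the shift of all genes, called each list lower (adjusted p = 0.001, 7.22e-06 and 1.2e-07 in this order). Of 19 hypoxia and glycolysis genes 15 fell and 4 did not pass (12 fell and 3 rose after median-of-ratios scaling). The glucose transporter Slc2a1 fell from 191 ± 48.1 to 68 ± 3.93 RPKM (SD, n = 4), and hexokinase Hk2 from 28.8 ± 3.72 to 13 ± 1.3. The oxygen sensor Egln3 fell from 118 ± 22.4 to 53.4 ± 4.73, and aldolase Aldoa from 621 ± 23.6 to 459 ± 12.4. Of 13 heat shock genes 9 fell, 3 rose and 1 did not pass (7 fell and 4 rose after median-of-ratios scaling). The chaperones Hsph1, Hspe1 and Hsp90aa1 fell from 87.7 ± 0.712 to 34.4 ± 2.15, from 182 ± 4.15 to 93.6 ± 3.99 and from 598 ± 21.5 to 290 ± 17.6. Hspa1b fell from 109 ± 19 to 18 ± 1.83, and its near-identical copy leaves that level uncertain. Of 8 Notch genes 7 fell and 1 rose under both scalings. The ligands Jag1 and Jag2 fell from 4.01 ± 0.189 to 1.62 ± 0.102 and from 3.36 ± 0.166 to 0.932 ± 0.266, and the targets Hey1 and Nrarp from 1.77 ± 0.113 to 0.236 ± 0.0396 and from 1.01 ± 0.2 to 0.0528 ± 0.0275. Counts were the same adjusted over the list alone. Camera gave adjusted p = 0.0786, 0.256 and 0.105 for the 3 lists in this order, and adjusted p = 0.696, 0.690 and 0.549 with an estimated correlation. The hypoxia list was called without the library labelled Ad-control replicate 2 (0.0423) and after quantile normalization (0.00591), which also called the heat shock list (0.0191). The highest values over 20 settings were 0.13 and 0.291 for these 2 lists.

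Among kallikreins and the protease-activated receptors that such proteases can cleave, 2 listed genes besides Klk8 were expressed above 0.5 RPKM. F2r, the thrombin receptor PAR1, rose from 94.5 ± 8.25 to 138 ± 19.9 RPKM (SD, n = 4, limma adjusted p = 0.000363). Klk10, a related secreted protease, was 0.533 ± 0.143 and 0.812 ± 0.174 RPKM and passed the test (adjusted p = 0.0363), adjusted over the list alone as well. That call was lost without the library labelled Ad-control replicate 4 (0.0945) or Ad-KLK8 replicate 1 (0.108), 3 (0.0746) or 4 (0.0536). It was also lost after rescaling RPKM to TPM (0.0518), in a voom fit of the recovered reads (0.0754) and with close libraries averaged (0.172), while its log2 change stayed between 0.17 and 0.60. F2rl1, which encodes PAR2, had 17 reads over the libraries labelled Ad-control and 0 over those labelled Ad-KLK8. With a floor of 3 reads over the group in place of 0, that is 6.4-fold lower. The counting error of the 17 reads is left out, so this is not a lower bound.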

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

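The tests in this part were chosen after their results were seen, except the check of gene length and GC content, and the scalings and the fits without 1 library that they draw on were set in advance. A library was singled out where its gap to the nearest of its group exceeded Dixon's 95% critical share of the group's range. Chance does so in about 1 of 20 groups, which gives 9.8 of the 195 groups tested, and 17 were found.

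Klk8 was high in all 8 libraries, and in the group labelled Ad-KLK8 replicate 2 stood apart at 3263 RPKM against 1159 to 1354, a gap of 0.907 of the range. An exchange of single libraries between the groups is argued against by the lowest correlation within a group, 0.9931, which lay above the highest between groups, 0.9411. Sharing that left part of the reads on another kallikrein gene is argued against as well, since no other kallikrein reached more than 0.0914% of the lowest Klk8 level. Reads of another kallikrein counted wholly on Klk8 would leave that gene near 0, so these levels cannot decide on them. An introduced KLK8 whose reads were not counted on the mouse gene cannot be told apart from one that was little expressed, because the 95% interval of the Klk8 log2 change (−0.31 to 0.92) includes 0. The treatment named in the labels and a wrong label of a whole group also stay open, as neither was tested.

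Most endothelial identity genes were near 0 while fibroblast and mesothelial markers were abundant in both groups, as were several of the 7 venous markers (medians 12.6 and 13.1 RPKM). A minor admixture of other cells is argued against for the identity genes, since the median of the endothelial identity list was at most 0.556% of the fibroblast median in either group. Under the filter were 17 of 25 endothelial genes (68.0%), compared with 0 of 87 matrix, cytoskeleton, ribosomal protein and oxidative phosphorylation genes (Fisher's exact p = 2.01e-14). These counts argue against a loss of whole genes in mapping or counting at the same rate in all lists. They do not address a partial loss. An equal share lost from all genes cancels in RPKM, and abundant genes would still pass the filter. No biological explanation was tested. A loss limited to low or particular genes, which the mostly abundant genes of that comparison do not address, cells of another type or a loss of endothelial identity may each give these levels, and no reference library of endothelium was analysed here.

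The fall of DNA replication genes had the largest median change of the 33 tested lists. Scaling between libraries is argued against as its whole cause, since the list median nearest 0 over 4 other scalings was −2.22. A bias of gene length or GC content is argued against too, since removing a smooth trend on both over all tested genes left a median of −2.33, with quartiles of −2.69 and −1.78, against −2.43 before. The replication median lay 0.96 below that of the G2/M list (difference −0.96 at a pseudocount of 0.1, permutation p = 2e-05 over 100000 resamples of genes, which are not independent). This argues only against a cause that lowers both lists by the same factor. It cannot decide on a lower share of dividing cells, since genes with different levels in cells that do not divide would fall by different amounts. A difference in growth state that came with the labelled treatment, or with an unrecorded batch of culture or sequencing, may remain, as the groups hold no library that would part them.

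Chance is argued against for the gene counts only as far as the 8 libraries are independent, which the labels do not state and the closely similar libraries leave open. Of the 35 splits of the libraries into 4 and 4, only the real one reached 9322 genes past the threshold with limma. Only it reached 1464 genes changed at least 2-fold, and the highest of the other splits was 0 in both cases. Each other split mixes the labelled groups, so counts of 0 would follow for any groups lying this far apart, whatever parted them. The smallest two-sided exact p that 4 against 4 libraries can give is 0.0286. At an unadjusted p under 0.05 the real split gave 9502 genes and the highest of the others 712. Chance cannot be excluded for the count of 9 gene lists, since 13 of the 35 splits gave at least as many and the highest of the others gave 15.

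Replicate 2 of the group labelled Ad-KLK8 stood apart in 9 of the 17 cases, Klk8 included. It was higher for F2r (167.7 RPKM against 126.4 to 131.2, gap 0.884), Pcna (0.872) and Ccna2 (0.884). It was lower for Irf7 (0.861), Parp9 (0.901), Ifit1 (458.8 RPKM against 755.1 to 784, gap 0.911), Timp3 (0.954) and Cdh5 (gap 0.989), where it had 0 reads against 1 read in each of the others. Ad-control replicate 4 was apart for Sprr2h (92.22 RPKM against 54.07 to 58.99, gap 0.871), Areg (0.847), Klk10 (0.901) and Parp9 (0.943). Ad-control replicate 2 was apart for Top2a (0.831), Ad-KLK8 replicate 1 for Serpinb2 (0.987), and Cldn5, with at most 1 read per library, set apart Ad-control replicate 3 (1.0) and Ad-KLK8 replicate 3 (0.951). Without Ad-KLK8 replicate 2 the comparison gave 9397 genes past the threshold and 1496 changed at least 2-fold.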

How the results depend on the processing

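The voom fit, the averaging of close libraries and the pathway alternatives were chosen after the data were seen, the others in advance. An edgeR test of counts was planned but not run, because the deposited unit is RPKM, and the voom fit of recovered reads stands in its place. The count of genes past the threshold stayed between 8187 and 10668 in all settings except a minimum of 5 RPKM, where fewer genes were tested and 6404 passed. Leaving out 1 library gave 8943 to 9397. Fits with the replicate number as a block gave 9170 genes. Same-numbered libraries did not deviate together (r = −0.091 to 0.011). No library labelled Ad-control correlated best with the library labelled Ad-KLK8 of its own number. The block changed no call of a named gene, while it brought the NF-kB list past the camera threshold (0.0485). The 2-fold count of 1464 became 2301 at a pseudocount of 0.1 and 2420 with voom, where low genes are shrunk less, and 930 at a minimum of 5 RPKM, where fewer genes were tested. It was 1437 to 1507 with 1 library left out. The Klk8 log2 difference ran from −0.036 to 0.461 with 1 library left out, negative only without Ad-KLK8 replicate 2. It was 0.527 after median-of-ratios scaling (exact p = 0.0857) and passed in no setting. With the replicate block it could not have passed, as the smallest possible exact p there was 0.125.

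Of 91 tested named genes, 86 kept direction and call in each setting that tested them. Most of these genes were picked for a small adjusted p or a large change, which favours such stability. Over all genes, 7755 of the 9322 calls were shared after median-of-ratios scaling and 7415 after quantile normalization. A minimum of 1 RPKM tested 86 of the 91, and a minimum of 5 RPKM tested 80. Of 2073 values under alternatives, 2059 kept both, 9 lost the call, 3 gained it and 2 turned, which were Klk8 as given and Icam1 at 0.031 after median-of-ratios scaling. The 9 lists past the threshold became 0 with an estimated correlation. Fry, which asks another question, called 25 lists, but the interferon list was not among them (adjusted p = 0.0697). The 9 KEGG pathways with an adjusted p under 0.001 stayed under 0.05 in 20 of 20 settings, with chemical carcinogenesis the highest at 0.0111 without filter, where its median was −0.002 with 21 genes higher and 12 lower. They were lost with an estimated correlation (0.686 to 0.729).

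Lists whose direction turned were not past the camera threshold in the main setting, and for most the cause was not tested. With fry the turned directions had adjusted p = 0.00405 for endothelial junctions, 0.00199 for glycocalyx, 0.361 for endothelial-to-mesenchymal transition, 0.000563 for the unfolded protein response, 0.000184 for KLF targets, 0.489 for cytoskeleton, 0.196 for ribosomal proteins and 0.489 for macrophage markers. Fry does not subtract the shift of all genes, and camera does. Without filter the values were 0.948 for endothelial identity and 0.948 for macrophages. At a minimum of 1 RPKM VEGF genes gave 0.993, and at 5 RPKM VEGF genes gave 0.433, ribosomal proteins 0.993 and macrophages 0.993. Upper-quartile scaling gave 0.774 for KLF targets, 0.33 for oxidative phosphorylation and 0.675 for macrophages. Median-of-ratios scaling gave 0.723, 0.175 and 0.604 in this order. Quantile normalization gave 0.984 for the unfolded protein response, 0.645 for KLF targets, 0.787 for cytoskeleton, 0.807 for macrophages and 0.00872 for a fall of ribosomal proteins. Rescaling to TPM gave 0.868 for ribosomal proteins, averaging close libraries 0.94 for KLF targets, and the replicate block 0.984 for macrophages. With 1 library left out, KLF targets ranged from 0.878 to 0.995, ribosomal proteins from 0.504 to 0.995 and macrophages from 0.711 to 0.999. Depth limits low genes such as Cdh5 and Cldn5, which rest on 24 and 1 reads in the libraries labelled Ad-control.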

Other observations

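The pathway test and the genes singled out in this part were chosen after the data were seen. Among 292 KEGG pathways, those of RNA handling and ribosome production were lower in the libraries labelled Ad-KLK8. Of 146 RNA transport genes 126 fell and 6 rose (101 and 17 after median-of-ratios scaling), of 125 spliceosome genes 100 fell and 4 rose (86 and 18), and of 69 genes of ribosome biogenesis 62 fell and 3 rose (55 and 6). The nuclear export receptor Xpo1 fell from 49.9 ± 2.64 to 16.4 ± 0.843 RPKM (SD, n = 4), the splicing factors Srsf7 and Srsf3 from 62.4 ± 3.14 to 17.2 ± 0.822 and from 71 ± 4.24 to 24.8 ± 0.942. The nucleolar genes Nop58 and Gnl3 fell from 106 ± 2.23 to 35.1 ± 1.95 and from 69.3 ± 1.33 to 18.9 ± 1.91. Camera gave adjusted p = 1.22e-06 for RNA transport and 1.75e-06 for the others, and adjusted p = 0.687 to 0.729 with an estimated correlation. The KEGG DNA replication (33 of 35 lower) and cell cycle (90 of 119 lower) pathways were called too, with adjusted p = 1.75e-06 and 0.000721, and adjusted p = 0.686 and 0.724 with an estimated correlation. Larger KEGG pathways close in name to some lists were not called, among them Notch signaling (40 genes, median 0.052, camera upward, adjusted p = 0.395), apoptosis (119 genes, −0.201, 0.766) and MAPK signaling (223 genes, −0.246, 0.923).

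Pathways of the lysosome, of branched-chain amino acid degradation and of xenobiotic metabolism were higher, whereas the RNA degradation pathway was lower (71 genes, median log2 change −0.49, camera adjusted p = 0.0169, and adjusted p = 0.686 with an estimated correlation). Of 107 lysosome genes 56 rose and 22 fell (75 and 13 after median-of-ratios scaling), among them Hexa, a lysosomal hexosaminidase, from 44.2 ± 2.25 to 101 ± 4.41 RPKM (SD, n = 4), and its activator Gm2a from 16.2 ± 1.3 to 33.6 ± 0.366. Of 45 genes for degradation of valine, leucine and isoleucine 23 rose and 8 fell (33 and 4), with Bckdha of the branched-chain dehydrogenase at 10.4 ± 0.807 and 24.8 ± 1.54 and Aldh6a1 at 11.3 ± 0.465 and 25.1 ± 0.454. Bcat1, the cytosolic transaminase of the same pathway, fell from 10.9 ± 1.34 to 2.05 ± 0.335. Of 29 genes of xenobiotic metabolism 22 rose and 4 fell (24 and 4), with the epoxide hydrolase Ephx1 rising from 166 ± 12.9 to 301 ± 12. Camera gave adjusted p = 2.9e-05 for each of these 3 pathways and 0.000242 for the overlapping pathway of chemical carcinogenesis, and adjusted p = 0.686 with an estimated correlation.

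Genes of the unfolded protein response went in both directions. Of 23 members 12 rose, 9 fell and 2 did not pass (13 rose and 8 fell after median-of-ratios scaling), with the same count adjusted over the list alone. Atf3, Chac1, Trib3 and Ppp1r15a, known as stress-induced targets of ATF4, fell from 38.2 ± 5.07 to 2.96 ± 0.416 RPKM (SD, n = 4), from 51.2 ± 3.87 to 9.67 ± 1.25, from 42.9 ± 3.17 to 9.91 ± 1.17 and from 73.1 ± 3.35 to 23.5 ± 1.21. Atf4 itself fell from 256 ± 7.48 to 115 ± 13. Calr, Dnajc3 and Pdia4, known as chaperone and folding genes and picked for their direction, rose from 432 ± 17.4 to 695 ± 18.3, from 20.4 ± 1.65 to 33.8 ± 0.726 and from 108 ± 2.09 to 143 ± 2.88. The list median was 0.14 and its mean −0.40, and camera gave adjusted p = 0.306 upward, and adjusted p = 0.690 with an estimated correlation. No difference between parts of the list was tested. Saa3, an acute-phase serum amyloid, had the highest level of any tested gene and rose from 9739 ± 1094 to 23709 ± 2349 RPKM.

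Other lists were not past the camera threshold in the main setting. Of their tested members the rises and falls were 8 and 7 of 18 for TGF-beta targets (adjusted p = 0.0709), 2 and 12 of 19 for p53 targets (0.256), 4 and 9 of 14 for NRF2 targets (0.74), 5 and 10 of 15 for VEGF signalling (0.895) and 4 and 6 of 11 for KLF targets (0.982). They were 7 and 8 of 19 for endothelial-to-mesenchymal transition (0.355), 6 and 7 of 18 for cytoskeleton (0.327), 2 and 9 of 20 for oxidative phosphorylation (0.861) and 1 and 6 of 24 for ribosomal proteins (0.904). After median-of-ratios scaling the first 5 became 10 and 4, 5 and 9, 4 and 8, 5 and 10, and 4 and 5, and the last 4 became 8 and 7, 9 and 4, 10 and 1, and 13 and 1. Camera's direction was upward for KLF targets, endothelial-to-mesenchymal transition, cytoskeleton and ribosomal proteins, while their median and mean changes were below 0. Antigen presentation genes showed 5 rises and 2 falls among 11, or 3 and 1 adjusted over the list alone and 7 and 1 after median-of-ratios scaling, and camera gave adjusted p = 0.0709. That list was called without Ad-KLK8 replicate 2 (0.000795) and at a minimum of 1 RPKM (0.0316) or 5 RPKM (0.0485), over a range of 0.000795 to 0.574 in 20 settings, and also with sample weights (0.0168), which were not among these. With an estimated correlation it had adjusted p = 0.690.

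Markers of further cell types were given by 1 rise and 5 falls of 6 pan-leukocyte genes (adjusted p = 0.861), 2 and 2 of 8 smooth muscle genes (0.306) and 1 and 3 of 6 venous genes (0.904). After median-of-ratios scaling these became 1 and 2, 5 and 1, and 2 and 3. Macrophage markers had an adjusted p of 0.982. Adjusted over the list alone, macrophage markers showed 1 rise and 5 falls and ribosomal proteins 1 and 5. Lists with under 5 tested genes showed 3 rises and 1 fall for arterial, 2 and 2 for lymphatic, 0 and 2 for capillary, and 1 and 1 for lung epithelial markers (2 and 1 after median-of-ratios scaling, with the others as given). They showed 1 fall for neutrophil and 1 rise for erythroid markers, and 2 rises among 4 tested histone genes. No lymphocyte marker reached the filter. None of the 9 listed mitochondrially encoded genes was matched by symbol among the deposited genes, so that list could not be analysed. The groups did not overlap for 8661 genes (72.2% of those tested), where chance gives 2.86%.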
